A study of Mus musculus with 30 samples.

How the data were processed

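RNA sequencing was carried out on 30 libraries of 4T1-tdTomato cells, a mouse mammary carcinoma line of BALB/c origin that carries a red fluorescent protein. Per the labels, the cells were taken from female BALB/c or NSG mice and sorted as DAPI-negative, CD45-negative and tdTomato-positive single cells. The NSG strain lacks T, B and NK cells. For tumours, 200000 cells were placed in the mammary fat pad, and for lung samples 500000 cells were injected in the tail vein. The 6 groups held 5 libraries each: BALB/c tumour (days 21 and 22), NSG tumour (day 10), BALB/c DTC and NSG DTC (lung, day 7), BALB/c macro-met (lung, days 21 and 23) and NSG macro-met (lung, days 19 and 20). Route, organ and cell number changed together between tumours and lung samples, and the day of tumours and of macro-mets differed between the strains, so these cannot be separated from stage or strain. The labels do not say whether the libraries came from separate animals, and they give no pairing or sequencing batch. The numbers in the library titles did not overlap between groups, so an effect of whatever they number cannot be separated from group.

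The deposited files were a table of raw counts per Ensembl gene and a table of TPM values for the same libraries. Per the labels, the authors listed Trimmomatic 0.36 and STAR 2.5.2b with the mouse assembly GRCm38/mm10. The counting tool, the strand setting and the annotation release behind the deposited counts were not stated, nor were the gene lengths behind the authors' TPM values. The count table held whole numbers for 49315 genes, of which 49056 had an ID in GENCODE M21. That release gave positions, GC content and exonic length. Without molecular identifiers, reads are not independent molecules. Library spread within groups, pooled over all 6, not counting error, sets the precision of each change.

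Genes with low counts were removed with filterByExpr by group, which left 17774 genes holding 99.969% of all counts. Libraries were scaled by TMM, and negative binomial models with 1 mean per group were fitted to all 30 libraries with the robust quasi-likelihood pipeline of edgeR 4.0.16 in R 4.3.3 (24 residual degrees of freedom, median biological coefficient of variation 0.269). Of the 11 comparisons, 9 set 1 group against another and 2 were interaction terms that asked whether a change between stages differed between the strains. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Levels are given as CPM (TMM-scaled), and changes as log2 fold changes with the standard error (SE) of the fit.

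The 30 gene lists, 20 of cell programmes and 10 of markers of other cell types, were written from textbook knowledge, and so were the comparisons, the tests and the rule for named genes, before the data were examined. Of the 633 list genes written, 626 were found in the count table and 594 were tested. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 30 lists of a comparison. Camera with a correlation estimated from the data and fry, which asks whether a list moves on balance in 1 direction, were run beside it. Members were counted as called over all genes tested and also adjusted over the list alone. Marker lists were compared between groups as mean log2 CPM per library with 2-sided exact permutation tests, adjusted over the 10 marker lists (smallest possible p with 5 against 5 0.00794).

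Named genes followed a rule. Fas, Nr3c1, Fkbp5, Tsc22d3 and Per1 were reported in each comparison, because the series title names glucocorticoids and Fas. Next came the 5 largest rises and 5 largest falls (3 and 3 in 6 of the 11 comparisons) among called genes with a mean log2 CPM of at least 3, groups without overlap between the libraries, no place in a marker list and a symbol that is not a predicted or clone name. The rule also took members of called programme lists with the smallest adjusted p, the most abundant markers of called marker lists, and at most 2 members of programme lists that were not called. The list of genes printed was taken from those that the rule allowed after their values were seen. Among the counted genes, 97 IDs repeated the name of another ID, and such names were not used, which left out 1 gene that the rule took. A further 3 genes that it took are not reported here. Members of paralog families (H2-K, H2-Q and H2-T, Gbp, Tgtp) can share reads, so their values are less certain than those of single genes. Genes whose counts were 0 in every library of a group were not named, but they enter medians of marker lists, which are therefore approximate.

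In several groups the log2 CPM values followed the GC content or the length of genes. The rank correlation across genes, between each library's departure from the mean of all libraries and GC content, ran from -0.744 to 0.589. Each comparison was therefore also fitted with offsets per library from a spline trend (5 degrees of freedom) on GC content and log2 length, available for 99.68% of the tested genes. This correction was chosen after seeing the data, as were fits without the 4 libraries that detected the fewest genes (gene-poor libraries: BALB/c tumour replicate 4, NSG macro-met replicate 3, NSG tumour replicates 2 and 3) and without the 2 BALB/c DTC libraries with the most lung epithelium marker RNA (lung-rich libraries: replicates 1 and 2). The 10 alternatives chosen beforehand were RLE size factors, no filter on low counts, DESeq2 1.42.0, voom with sample quality weights, limma-trend on 2 TPM scales, log2(TPM + 1) and log2(TPM + 0.1), the mean of all marker lists as a covariate, only the libraries of the comparison, a fold change of at least 2, and leaving out each library in turn.

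The pipeline was tested on simulated counts with the mean level of each gene over the 30 libraries, the real library sizes and the fitted dispersions, in which 200 genes were changed in the BALB/c DTC libraries. edgeR recovered 32.8% of changes of 1.5-fold, 77.6% of changes of 2-fold and 93.9% of changes of 4-fold, and called 10 of the unchanged genes. With a trend on GC content and length, of a size set by hand, laid over those libraries, 5784 of 17574 unchanged genes were called without offsets and 1 with them, while recovery went from 159 to 136 of the 200 changed genes. Counts of called genes are therefore given both ways. Of 3 lists raised 1.5-fold, camera with either correlation and fry called 2 and no other list. Genes were simulated as independent of each other, so this cannot show which inter-gene correlation suits the real data.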

Results

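Messenger RNA levels were measured in 30 libraries of sorted 4T1-tdTomato cells, 5 in each of 6 groups formed by strain of the host (BALB/c or NSG) and by site and stage (tumour, DTC, not expanded in the labels, from lung at day 7, and macro-met from lung). Total counts per library were 34070188 to 65621525 in BALB/c tumours, 35162230 to 60327229 in BALB/c DTC, 33649294 to 61780104 in BALB/c macro-mets, 29832098 to 65430982 in NSG tumours, 34632933 to 57813345 in NSG DTC and 34582968 to 61037353 in NSG macro-mets. Correlations of log2 CPM within groups ran from 0.8918 to 0.9867. Values in parentheses after gene names are log2 fold changes ± SE with n = 5 per group, and medians are of log2 fold changes over a list, whose p is from camera and adjusted with either correlation. Other members of a list were not called, and members called when adjusted over the list alone are counted where that number differs.

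The series title names glucocorticoids and Fas, and the plot of 6 key genes shows their levels. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, stood at 54.1 ± 10.1 CPM (SD, n = 5) in BALB/c tumours, 101 ± 35.2 in BALB/c DTC and 255 ± 85.4 in BALB/c macro-mets, and at 59.3 ± 3.47, 106 ± 13.5 and 398 ± 133 in the matching NSG groups. Fkbp5, a co-chaperone of the glucocorticoid receptor that glucocorticoids induce, stood at 129 ± 29, 163 ± 21.2 and 298 ± 28.6 CPM in BALB/c tumours, DTC and macro-mets, and at 176 ± 16.1, 141 ± 17.8 and 403 ± 29.7 CPM in NSG mice. Fas, the death receptor bound by Fas ligand, stood at 18.1 ± 4.88, 14.4 ± 3.63 and 11.7 ± 1.92 CPM in BALB/c mice and at 6.91 ± 1.58, 7.72 ± 1.11 and 4.92 ± 1.77 CPM in NSG mice. On GRCm38 Fas (ENSMUSG00000024778) lies on chromosome 19 from 34290666 to 34327772, Tsc22d3 (ENSMUSG00000031431) on chromosome X from 140539528 to 140600659, Fkbp5 (ENSMUSG00000024222) on chromosome 17 from 28399094 to 28517527 and Nr3c1 (ENSMUSG00000024431) on chromosome 18 from 39410545 to 39519421.

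**Figure D1:**
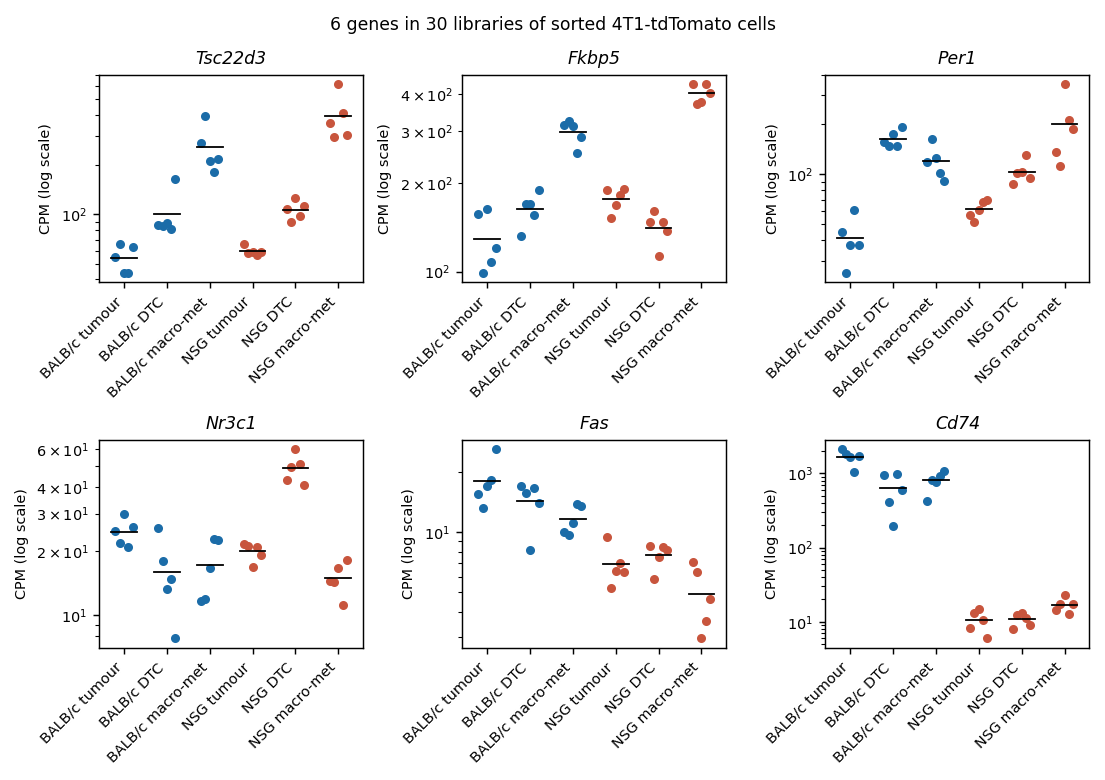
Level of Tsc22d3, Fkbp5, Per1, Nr3c1, Fas and Cd74 in CPM on a log axis, with a dot per library, a bar at the mean, BALB/c in blue and NSG in red. Mean Cd74 lay between 629 and 1670 CPM in the BALB/c groups and between 10.5 and 17 CPM in the NSG groups.

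BALB/c DTC were compared with BALB/c tumours to ask how cells in the lung for 7 days differed from the primary site. The replication, mitosis, NF-kB and cholesterol synthesis lists rose in DTC, while the hypoxia response and MHC class II lists fell (adjusted p = 0.0352 to 0.346 with an estimated correlation). Tsc22d3 rose (0.90 ± 0.21, adjusted p = 0.00101), as did the clock gene Per1 (2.00 ± 0.23, adjusted p = 8.68e-08) and Fkbp5 (0.33 ± 0.12, adjusted p = 0.0284). Nr3c1, the glucocorticoid receptor gene, fell (-0.63 ± 0.21, adjusted p = 0.0182), and Fas was not called (-0.33 ± 0.22, adjusted p = 0.232). The 5 largest rises were Stra6 (3.81 ± 0.36), the receptor for retinol-binding protein, the cytokine gene Tnf (3.67 ± 0.36), Extl1 (3.57 ± 0.47), an exostosin-like glycosyltransferase, the Wnt ligand gene Wnt10a (3.29 ± 0.26) and the neutrophil chemoattractant gene Cxcl2 (3.24 ± 0.56). The 5 largest falls were Ibsp (-5.18 ± 0.44), bone sialoprotein, the membrane protease gene Tmprss6 (-4.11 ± 0.38), Gpnmb (-3.79 ± 0.38), a transmembrane glycoprotein, the mitophagy receptor gene Bnip3 (-3.56 ± 0.33) and the Hedgehog co-receptor gene Boc (-3.39 ± 0.31) (largest adjusted p = 4.01e-05 of these 10).

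First, 31 of 33 DNA replication genes rose (median 1.47, adjusted p = 3.73e-28 and p = 0.0352 with an estimated correlation). Among them were the helicase genes Mcm10 (2.41 ± 0.14), Cdc45 (2.15 ± 0.14) and Mcm5 (2.21 ± 0.16). Similarly 25 of 30 mitosis genes rose (27 higher adjusted over the list alone, median 1.31, adjusted p = 1.81e-14 and p = 0.224 with an estimated correlation). Examples were the mitotic kinase genes Aurkb (2.62 ± 0.20) and Aurka (2.14 ± 0.18). Further, 22 of 27 NF-kB target genes rose (median 1.39, adjusted p = 4.54e-09 and p = 0.224 with an estimated correlation). Members included the adhesion molecule gene Icam1 (2.54 ± 0.25) and Nfkb2 (1.39 ± 0.16), an NF-kB subunit. Also, 20 of 24 cholesterol synthesis genes rose (22 higher adjusted over the list alone, median 0.84, adjusted p = 1.17e-09 and p = 0.233 with an estimated correlation). These included squalene epoxidase, Sqle (1.36 ± 0.16). Besides, 19 of 34 oxidative phosphorylation subunits rose (21 higher adjusted over the list alone, median 0.29, adjusted p = 4.69e-06 and p = 0.357 with an estimated correlation). By contrast 15 of 23 hypoxia response genes fell and 4 rose (4 higher and 16 lower adjusted over the list alone, median -1.09, adjusted p = 4.69e-06 and p = 0.279 with an estimated correlation). They included Ankrd37 (-3.08 ± 0.29) and Bnip3l (-1.25 ± 0.12). Next, 8 of 10 MHC class II genes fell (9 lower adjusted over the list alone, median -1.58, adjusted p = 0.000984 and p = 0.346 with an estimated correlation). Among them were H2-Eb1 (-1.94 ± 0.40), the peptide-loading gene H2-DMb1 (-1.85 ± 0.39) and the invariant chain gene Cd74 (-1.41 ± 0.31). As a group, 10 of 27 glucocorticoid-induced genes rose and 4 fell (median 0.33, adjusted p = 0.089). Lung RNA moved with these groups, since 14 of 16 lung epithelium markers rose and 1 fell (median 7.31, adjusted p = 2.24e-07 and p = 0.224 with an estimated correlation). Likewise 14 of 15 endothelial markers rose (median 3.84, adjusted p = 1.77e-07 and p = 0.279 with an estimated correlation). Examples were surfactant protein C, Sftpc (9.87 ± 1.41), and Pecam1 (3.58 ± 0.73). Mean log2 CPM (DTC minus tumours) differed for lung epithelium (4.97), endothelial (3.62), neutrophil (1.94) and red cell (1.79) markers (exact permutation, adjusted p = 0.0265 to 0.0398).

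Calls numbered 7357 of 17774, 3621 higher and 3736 lower, against 3484 higher and 3945 lower with GC and length offsets. With the offsets Fkbp5 was 0.15 and Nr3c1 -0.09, neither called, nor were Fkbp5 with voom (0.29) or, with only these libraries, Fkbp5 (0.34) or Nr3c1 (-0.63), Fkbp5 also lost its call without any 1 of BALB/c tumour replicates 2, 4 and 5 and BALB/c DTC replicates 2 to 5 (0.23 to 0.33) and without the 4 gene-poor libraries (0.30), with marker genes as a covariate Fkbp5 was 0.61, Nr3c1 -1.22, Sftpc 4.93 and Pecam1, not called, 0.39, without the 2 lung-rich libraries (the BALB/c DTC with most lung RNA) Nr3c1 was -1.06 and Pecam1, not called, 1.27, Cxcl2 was 4.89 with voom and Pecam1 2.06 on log2(TPM + 1), and the glucocorticoid-induced list was called with fry, without the 4 gene-poor libraries and without BALB/c tumour replicate 4.

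BALB/c macro-mets were compared with BALB/c DTC to follow cells in lung from day 7 to the later stage. The hypoxia response and glycolysis lists rose in macro-mets, while the replication, mitosis, NF-kB, interferon response and epithelial lists fell (adjusted p = 0.132 to 0.43 with an estimated correlation). Tsc22d3 rose further (1.34 ± 0.21, adjusted p = 1.33e-05), and so did Fkbp5 (0.87 ± 0.12, adjusted p = 2.2e-06). Per1 (-0.44 ± 0.22, adjusted p = 0.134), Nr3c1 (0.11 ± 0.21, adjusted p = 0.737) and Fas (-0.30 ± 0.22, adjusted p = 0.329) were not called. The 5 largest rises were the coagulation factor gene F5 (5.25 ± 0.62), Lbp (4.75 ± 0.30), the lipopolysaccharide-binding protein, Bnip3 (4.00 ± 0.34), the noradrenaline transporter gene Slc6a2 (3.96 ± 0.29) and the acute phase gene Saa2 (3.92 ± 0.56). The 5 largest falls were the keratin gene Krt16 (-4.49 ± 0.74), the serpin gene Serpina3g (-4.15 ± 0.55), Extl1 (-3.72 ± 0.48), the ubiquitin ligase gene Neurl3 (-3.45 ± 0.25) and Nppb (-3.37 ± 0.37), the precursor of brain natriuretic peptide, with a largest adjusted p = 3.96e-05 among these 10.

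First, 18 of 23 hypoxia response genes rose (18 higher and 1 lower adjusted over the list alone, median 1.27, adjusted p = 1.03e-13 and p = 0.132 with an estimated correlation). Examples were Pdk1 (2.58 ± 0.20), a kinase that restrains pyruvate dehydrogenase, and Bnip3l (1.36 ± 0.12). Likewise 12 of 16 glycolysis enzymes rose (13 higher adjusted over the list alone, median 0.63, adjusted p = 1.78e-05 and p = 0.403 with an estimated correlation). Members included Aldoc (1.72 ± 0.19) and Pgk1 (1.04 ± 0.17). Also, 26 of 33 DNA replication genes fell (29 lower adjusted over the list alone, median -0.64, adjusted p = 4.05e-12 and p = 0.291 with an estimated correlation). These included Mcm5 (-1.37 ± 0.15) and Cdc45 (-0.92 ± 0.13). Next, 24 of 30 mitosis genes fell (26 lower adjusted over the list alone, median -0.68, adjusted p = 1.49e-07 and p = 0.403 with an estimated correlation). Further, 18 of 27 NF-kB target genes fell and 1 rose (1 higher and 20 lower adjusted over the list alone, median -0.98, adjusted p = 5.8e-08 and p = 0.291 with an estimated correlation). They included Nfkb2 (-1.55 ± 0.16) and the cytokine gene Il1a (-4.27 ± 0.52). Further, 15 of 29 interferon gamma response genes fell (20 lower adjusted over the list alone, median -0.94, adjusted p = 6.45e-06 and p = 0.43 with an estimated correlation). Among them were the feedback inhibitor gene Socs1 (-1.81 ± 0.22) and the chemokine gene Cxcl11 (-2.99 ± 0.38). Likewise 19 of 32 type I interferon response genes fell (20 lower adjusted over the list alone, median -0.89, adjusted p = 1.82e-07 and p = 0.403 with an estimated correlation). Examples were Oas1a (-1.46 ± 0.17) and Isg15 (-1.28 ± 0.21). In turn, 14 of 21 epithelial genes fell (16 lower adjusted over the list alone, median -0.80, adjusted p = 2.93e-09 and p = 0.291 with an estimated correlation). Members included the keratin gene Krt19 (-2.11 ± 0.18), the tight junction gene Cldn7 (-1.24 ± 0.15) and the transcription factor gene Ovol1 (-3.33 ± 0.43). As a group, 5 of 27 glucocorticoid-induced genes rose and 3 fell (median 0.28, adjusted p = 0.338). The mean had the opposite sign (-0.0559). Of 16 lung epithelium markers 12 fell (median -4.09, adjusted p = 0.000117 and p = 0.403 with an estimated correlation), including Sftpc (-5.39 ± 1.13). Mean log2 CPM differed for skeletal muscle (-0.92) and adipocyte (-0.94) but not lung (-2.63) markers (exact permutation, adjusted p = 0.0397, lung 0.0793).

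Calls numbered 5471, 2949 higher and 2522 lower, against 3773 and 1754 on log2(TPM + 1), and 2791 and 3253 with the offsets. Sftpc was -2.19 and not called without the 2 lung-rich libraries and -2.95 with the covariate, and Per1 was called with voom (-0.50) and with only these libraries (-0.47), and the glucocorticoid-induced list with fry.

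Comparing BALB/c macro-mets with BALB/c tumours set late lung growth against the primary site. The replication and glucocorticoid-induced lists rose in macro-mets, while the MHC class II, interferon response and epithelial lists fell (adjusted p = 0.272 to 0.537 with an estimated correlation). Tsc22d3 (2.24 ± 0.22, adjusted p = 1.59e-08), Per1 (1.55 ± 0.23, adjusted p = 7.32e-06) and Fkbp5 (1.20 ± 0.12, adjusted p = 2.44e-08) rose. Fas fell (-0.63 ± 0.22, adjusted p = 0.0247), and Nr3c1 was not called (-0.52 ± 0.21, adjusted p = 0.0535). The 3 largest rises were Sod3 (3.24 ± 0.32), extracellular superoxide dismutase, Selenbp1 (2.85 ± 0.35), a selenium-binding protein, and Lbp (2.83 ± 0.27), and the 3 largest falls were titin, Ttn (-3.90 ± 1.08), and the non-coding RNA genes Rn7sk (-3.87 ± 1.10) and Malat1 (-2.96 ± 0.49) (largest adjusted p = 0.00742). Hsd11b1 (2.56 ± 0.41), the enzyme that regenerates active glucocorticoids, rose as well.

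As a group, 13 of 27 glucocorticoid-induced genes rose and 4 fell (median 0.51, adjusted p = 0.0104 and p = 0.522 with an estimated correlation). Next, 8 of 10 MHC class II genes fell (9 lower adjusted over the list alone, median -1.25, adjusted p = 0.00425 and p = 0.537 with an estimated correlation). They included the peptide-loading gene H2-DMa (-1.17 ± 0.29) and the transactivator gene Ciita (-1.31 ± 0.37). Further, 20 of 29 interferon gamma response genes fell and 1 rose (1 higher and 24 lower adjusted over the list alone, median -1.10, adjusted p = 4.34e-07 and p = 0.537 with an estimated correlation). An example was Gbp7 (-2.72 ± 0.52). Likewise 23 of 32 type I interferon response genes fell (24 lower adjusted over the list alone, median -0.78, adjusted p = 6.41e-08 and p = 0.537 with an estimated correlation). Examples were Oas2 (-2.16 ± 0.41). Also, 30 of 33 DNA replication genes rose and 1 fell (median 0.84, adjusted p = 8.07e-17 and p = 0.272 with an estimated correlation). Members included Mcm10 (1.46 ± 0.14). In turn, 12 of 21 epithelial genes fell (13 lower adjusted over the list alone, median -0.52, adjusted p = 1.51e-05 and p = 0.537 with an estimated correlation). These included Rab25 (-1.95 ± 0.28) and the splicing regulator gene Esrp1 (-1.10 ± 0.20). Mean log2 CPM differed for red cell (2.57), lung epithelium (2.35), endothelial (1.79), adipocyte (-1.24) and skeletal muscle (-1.74) markers (exact permutation, adjusted p = 0.0198 to 0.0318), the last far higher in replicate 4 than in the other tumours.

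Calls numbered 6726, 3483 higher and 3243 lower, against 4274 and 2450 on log2(TPM + 1), and 2926 and 3967 with the offsets. Fas was -0.38 and not called with the offsets and lost its call on either TPM scale and without BALB/c tumour replicate 5 (-0.46) or BALB/c macro-met replicate 1 (-0.60) or 2 (-0.58), and Ttn (-1.75) and Rn7sk (-1.58) lost theirs without BALB/c tumour replicate 4, as Ttn did on log2(TPM + 1) (-1.13), and were -1.94 and -1.72 with voom, Rn7sk was -2.38 and Oas2 -1.40 on log2(TPM + 1), while Nr3c1 (-0.04 with the offsets) was called with RLE and DESeq2 (both -0.58), voom (-0.47), the covariate (-0.80), only these libraries (-0.57) and without BALB/c tumour replicate 4 (-0.59) or BALB/c macro-met replicate 4 (-0.67) or 5 (-0.66).

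The same question was asked of NSG DTC and tumours. The mitosis, replication and type I interferon response lists rose in NSG DTC, while the hypoxia, glycolysis, ribosomal protein and MHC class I lists fell (adjusted p = 0.386 to 0.54 with an estimated correlation). Tsc22d3 (0.84 ± 0.21, adjusted p = 0.00332), Per1 (0.76 ± 0.22, adjusted p = 0.0122) and Nr3c1 (1.29 ± 0.22, adjusted p = 6.43e-05) rose, Fkbp5 fell (-0.32 ± 0.12, adjusted p = 0.0485), and Fas was not called (0.16 ± 0.22, adjusted p = 0.655). The 5 largest rises were the proliferation marker gene Mki67 (3.94 ± 0.43), the mitotic kinesin genes Kif20b (3.93 ± 0.56) and Cenpe (3.66 ± 0.46), the centromere gene Cenpf (3.78 ± 0.34) and Tppp (3.79 ± 0.38), a tubulin-binding protein. The 5 largest falls were Tmprss6 (-3.35 ± 0.36), Ramp1 (-2.21 ± 0.22), a receptor-modifying protein, the imprinted non-coding RNA H19 (-2.20 ± 0.26), the immediate early gene Fosb (-2.15 ± 0.38) and Lbp (-2.08 ± 0.26) (largest adjusted p = 0.000144 of these 10).

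First, 18 of 30 mitosis genes rose (median 0.54, adjusted p = 3.86e-07 and p = 0.431 with an estimated correlation). Next, 20 of 33 DNA replication genes rose (23 higher adjusted over the list alone, median 0.43, adjusted p = 1.93e-06 and p = 0.431 with an estimated correlation). Among them were Mcm10 (0.84 ± 0.14) and Mcm4 (0.76 ± 0.13). Further, 16 of 32 type I interferon response genes rose (18 higher adjusted over the list alone, median 0.68, adjusted p = 0.000148 and p = 0.54 with an estimated correlation). Examples were Mx1 (3.02 ± 0.44), Ifit3 (1.86 ± 0.29) and the RNA sensor gene Ddx58 (1.00 ± 0.19). Next, 10 of 22 MHC class I genes fell (median -0.27, adjusted p = 1.61e-05 and p = 0.431 with an estimated correlation). Members included H2-K1 (-0.67 ± 0.12) and H2-D1 (-0.69 ± 0.13). Next, 13 of 23 hypoxia response genes fell and 1 rose (1 higher and 14 lower adjusted over the list alone, median -0.64, adjusted p = 4.8e-08 and p = 0.386 with an estimated correlation). These included the collagen hydroxylase gene P4ha1 (-1.82 ± 0.20) and Ankrd37 (-2.53 ± 0.29). Next, 12 of 16 glycolysis enzymes fell (13 lower adjusted over the list alone, median -0.66, adjusted p = 4.39e-08 and p = 0.386 with an estimated correlation). They included Pfkl (-1.28 ± 0.20) and Tpi1 (-0.92 ± 0.15). Also, 36 of 36 ribosomal protein genes fell (median -0.48, adjusted p = 8.03e-19 and p = 0.386 with an estimated correlation). Among them were Rps18 (-0.65 ± 0.11) and Rpl13 (-0.65 ± 0.11). Also, 7 of 22 immediate early and heat shock genes fell (median -0.54, adjusted p = 0.000788 and p = 0.54 with an estimated correlation). Examples were Fos (-1.52 ± 0.22) and Junb (-1.14 ± 0.21). As a group, 4 of 27 glucocorticoid-induced genes rose and 3 fell (median -0.025, adjusted p = 0.47). Among single genes, Hsd11b2 (-1.38 ± 0.21), the enzyme that inactivates glucocorticoids, fell, and Sftpc (5.24 ± 1.29) rose. Mean log2 CPM differed for endothelial (3.29), lung epithelium (2.38), red cell (2.17), macrophage (0.86) and skeletal muscle (-1.08) markers (exact permutation, adjusted p = 0.0198 to 0.0476). The NSG DTC libraries departed from the others along GC content and length, as the plot of library properties shows.

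Calls numbered 4538, 2840 higher and 1698 lower, against 5001 and 787 on log2(TPM + 1), and 2023 and 2347 with the offsets, under which Nr3c1 was 0.47. The immediate early list was not called with fry, Per1 lost its call without NSG DTC replicate 4 (0.62), Fkbp5 lost its call without any 1 of NSG tumour replicates 1 and 3 to 5 and NSG DTC replicates 3 and 5 (-0.36 to -0.28) and on either TPM scale (both -0.11), with the covariate Fkbp5 (-0.13), Per1 (0.70) and Sftpc (3.10) were not called, nor was Sftpc with voom (5.72), and Fkbp5 was -0.49 without the 4 gene-poor libraries and on log2(TPM + 1) Mx1 was 1.21 and Rps18 and Rpl13 -0.43.

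**Figure D2:**
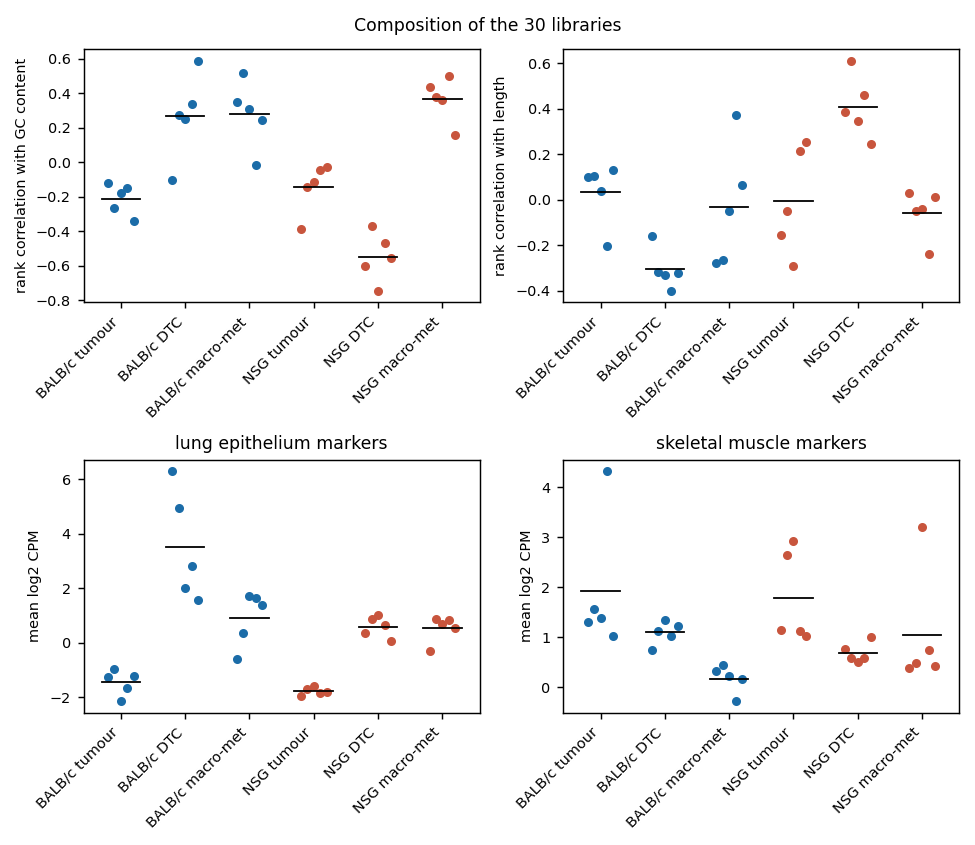
Rank correlation, across genes, of each library's departure from the mean library with GC content and with length, and mean log2 CPM of lung epithelium and skeletal muscle markers, with a dot per library. Correlations with GC content ran from -0.744 to -0.367 in NSG DTC and from 0.161 to 0.504 in NSG macro-mets.

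NSG macro-mets were compared with NSG DTC to follow the lung stages in NSG mice. The hypoxia response, glycolysis, MHC class I and glucocorticoid-induced lists rose in macro-mets, while the mitosis, type I interferon response and epithelial lists fell (adjusted p = 0.337 to 0.899 with an estimated correlation). Tsc22d3 (1.91 ± 0.21, adjusted p = 3.29e-08), Fkbp5 (1.51 ± 0.12, adjusted p = 1.98e-10) and Per1 (0.95 ± 0.22, adjusted p = 0.000891) rose, and Nr3c1 (-1.71 ± 0.22, adjusted p = 1.97e-07) and Fas (-0.65 ± 0.22, adjusted p = 0.0196) fell. The 3 largest rises were Lbp (5.23 ± 0.30), the matricellular protein gene Ctgf (4.03 ± 0.33) and Bnip3 (3.57 ± 0.33), and the 3 largest falls were Cenpe (-5.34 ± 0.50), the condensin gene Smc2 (-4.97 ± 0.50) and Aspm (-4.95 ± 0.41), a spindle pole protein (largest adjusted p = 9.47e-09).

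As a group, 12 of 27 glucocorticoid-induced genes rose and 2 fell (median 0.91, adjusted p = 0.00144 and p = 0.337 with an estimated correlation). Members included the arrestin-domain gene Arrdc2 (2.23 ± 0.23). Next, 12 of 22 MHC class I genes rose and 4 fell (13 higher and 4 lower adjusted over the list alone, median 0.53, adjusted p = 0.00101 and p = 0.899 with an estimated correlation). These included H2-K1 (1.18 ± 0.12). Further, 26 of 32 type I interferon response genes fell (27 lower adjusted over the list alone, median -1.46, adjusted p = 1.18e-09 and p = 0.517 with an estimated correlation). They included the RNA-activated kinase gene Eif2ak2 (-3.26 ± 0.37) and Ifit1 (-3.23 ± 0.40). Next, 19 of 23 hypoxia response genes rose and 1 fell (median 1.31, adjusted p = 9.66e-09 and p = 0.337 with an estimated correlation). Among them were P4ha2 (2.48 ± 0.22) and Pdk1 (2.09 ± 0.20). Next, 15 of 16 glycolysis enzymes rose (median 1.10, adjusted p = 1.08e-08 and p = 0.395 with an estimated correlation). Examples were Aldoc (2.07 ± 0.19). In turn, 14 of 21 epithelial genes fell (16 lower adjusted over the list alone, median -0.69, adjusted p = 0.000128 and p = 0.735 with an estimated correlation). Members included Krt19 (-1.78 ± 0.18) and Ovol1 (-3.62 ± 0.43). Also, 21 of 30 mitosis genes fell (22 lower adjusted over the list alone, median -0.79, adjusted p = 8.25e-09 and p = 0.517 with an estimated correlation). These included Cenpf (-4.91 ± 0.36) and Mki67 (-4.66 ± 0.44). Also, 24 of 36 ribosomal protein genes rose (26 higher adjusted over the list alone, median 0.35, adjusted p = 1.18e-05 and p = 0.947 with an estimated correlation). Mean log2 CPM differed for neutrophil (1.33) and endothelial (-1.15) markers (exact permutation, adjusted p = 0.0397).

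Calls numbered 7765, 3778 higher and 3987 lower, against 2765 and 5047 on log2(TPM + 1), and 3974 and 3575 with the offsets, which turned the direction of 400. With the offsets the glucocorticoid-induced and ribosomal protein lists, Fas (-0.08) and Per1 (0.56) were not called and Nr3c1 was -0.42, H2-K1 0.74 and Cenpf -3.23, while Fas also lost its call with voom (-0.44), without the 4 gene-poor libraries (-0.49) and without NSG macro-met replicate 3 (-0.53) or 4 (-0.57) and Per1 was 0.51 with voom and 0.62 without NSG macro-met replicate 3.

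NSG macro-mets were set against NSG tumours in the same way. The glucocorticoid-induced and hypoxia response lists rose in macro-mets, while the epithelial, type I interferon response and immediate early lists fell (adjusted p = 0.305 to 0.569 with an estimated correlation). Tsc22d3 (2.75 ± 0.22, adjusted p = 7.42e-10), Per1 (1.71 ± 0.23, adjusted p = 2.59e-06) and Fkbp5 (1.19 ± 0.12, adjusted p = 3.14e-08) rose. Nr3c1 (-0.42 ± 0.21, adjusted p = 0.141) and Fas (-0.49 ± 0.22, adjusted p = 0.1) were not called. The 3 largest rises were elastin, Eln (3.85 ± 0.71), Limch1 (3.67 ± 0.29), an actin-binding protein, and Sod3 (3.40 ± 0.32), and the 3 largest falls were Ovol1 (-4.80 ± 0.46), the adhesion molecule gene Alcam (-2.74 ± 0.29) and Neurl3 (-2.66 ± 0.25) (largest adjusted p = 0.000206).

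As a group, 12 of 27 glucocorticoid-induced genes rose and 3 fell (median 0.64, adjusted p = 0.00238 and p = 0.305 with an estimated correlation). They included Arrdc2 (1.84 ± 0.23). Among steroid enzymes Hsd11b1 (2.98 ± 0.41) rose and Hsd11b2 (-0.88 ± 0.21) fell. Next, 11 of 23 hypoxia response genes rose and 2 fell (14 higher and 2 lower adjusted over the list alone, median 0.65, adjusted p = 0.00307 and p = 0.569 with an estimated correlation). Among them were adrenomedullin, Adm (2.51 ± 0.38), and Selenbp1 (3.53 ± 0.36). In turn, 19 of 21 epithelial genes fell (median -0.86, adjusted p = 2.28e-12 and p = 0.305 with an estimated correlation). Examples were the keratin gene Krt7 (-1.33 ± 0.14) and Cldn4 (-2.04 ± 0.24). Further, 16 of 32 type I interferon response genes fell (18 lower adjusted over the list alone, median -0.66, adjusted p = 2.97e-06 and p = 0.569 with an estimated correlation). Members included Oas2 (-3.18 ± 0.45) and Usp18 (-1.67 ± 0.25). Also, 11 of 22 immediate early and heat shock genes fell and 3 rose (3 higher and 14 lower adjusted over the list alone, median -0.69, adjusted p = 0.000774 and p = 0.569 with an estimated correlation). These included Nr4a2 (-2.49 ± 0.37). Myeloid RNA moved with these groups, since 7 of 21 macrophage and monocyte markers rose (median 1.10, adjusted p = 0.00134 and p = 0.569 with an estimated correlation). They included lysozyme, Lyz2 (2.34 ± 0.79). Mean log2 CPM differed for lung epithelium (2.32), endothelial (2.14), macrophage (1.68) and red cell (1.63) markers (exact permutation, adjusted p = 0.0198).

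Calls numbered 5415, 2996 higher and 2419 lower, against 2986 higher and 2717 lower with the offsets. With the covariate Lyz2 (0.29) and Hsd11b2 (-0.56) were not called, Eln was 2.54 and Nr3c1 was called (-0.80), as it was with voom (-0.47) and only these libraries (-0.47) but not with the offsets (0.05), Oas2 was -1.33 on log2(TPM + 1), Lyz2 lost its call with no filter (2.35), without the 4 gene-poor libraries (2.49) and without NSG tumour replicate 1, 2 or 5 (2.17 to 2.26), and Fas gained one without NSG macro-met replicate 1 (-0.70).

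BALB/c DTC were compared with NSG DTC to ask how cells at day 7 in lung differed between the strains of host. The lack of T, B and NK cells cannot be told apart from other differences between the strains. The MHC class II, MHC class I, interferon response, oxidative phosphorylation and ribosomal protein lists were higher in BALB/c DTC, and the mitosis list was lower (adjusted p = 0.0812 to 0.612 with an estimated correlation). Fas (0.90 ± 0.22, adjusted p = 0.00173) and Per1 (0.66 ± 0.22, adjusted p = 0.0189) were higher in BALB/c DTC and Nr3c1 was lower (-1.63 ± 0.22, adjusted p = 1.14e-06). Tsc22d3 (-0.08 ± 0.21, adjusted p = 0.805) and Fkbp5 (0.21 ± 0.12, adjusted p = 0.179) were not called. The 5 largest positive differences were the MHC class II genes H2-Eb1 (8.36 ± 0.55), H2-Ab1 (8.20 ± 0.66) and H2-Aa (7.52 ± 0.66), Cd74 (5.87 ± 0.38) and the interferon-induced GTPase gene Gbp4 (4.76 ± 0.58). The 5 largest negative differences were the protease gene Tmprss11e (-3.24 ± 0.27), Cenpf (-3.21 ± 0.33), the chromatin remodeller gene Atrx (-3.15 ± 0.41), Cenpe (-3.13 ± 0.45) and the myosin gene Myo9a (-3.08 ± 0.37) (largest adjusted p = 3.68e-06 of these 10).

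First, 9 of 10 MHC class II genes were higher (10 higher adjusted over the list alone, median 6.69, adjusted p = 3.09e-14 and p = 0.0812 with an estimated correlation). Next, 19 of 22 MHC class I genes were higher and 1 was lower (19 higher and 2 lower adjusted over the list alone, median 1.22, adjusted p = 6.89e-15 and p = 0.0984 with an estimated correlation). Examples were the immunoproteasome genes Psmb9 (2.71 ± 0.18) and Psmb8 (1.90 ± 0.14) and H2-Q7 (1.95 ± 0.16). Further, 27 of 29 interferon gamma response genes were higher (median 2.84, adjusted p = 2.26e-20 and p = 0.0984 with an estimated correlation). Members included Igtp (3.84 ± 0.30) and the T cell chemoattractant genes Cxcl11 (5.35 ± 0.43) and Cxcl9 (7.65 ± 0.69). Likewise 19 of 32 type I interferon response genes were higher and 2 were lower (23 higher and 3 lower adjusted over the list alone, median 0.86, adjusted p = 1.41e-05 and p = 0.447 with an estimated correlation). These included Bst2 (2.00 ± 0.20), Ifi35 (1.07 ± 0.13) and Zbp1 (1.99 ± 0.26). Icam1 (2.11 ± 0.25) and the checkpoint ligand gene Cd274 (2.75 ± 0.33), which encodes PD-L1, were higher too. Also, 13 of 30 mitosis genes were lower (median -0.29, adjusted p = 0.0174 and p = 0.612 with an estimated correlation). They included Mki67 (-2.85 ± 0.40). Besides, 22 of 34 oxidative phosphorylation subunits were higher and 1 was lower (24 higher and 1 lower adjusted over the list alone, median 0.42, adjusted p = 6.55e-08 and p = 0.396 with an estimated correlation). Next, 31 of 36 ribosomal protein genes were higher (33 higher adjusted over the list alone, median 0.51, adjusted p = 3.39e-12 and p = 0.433 with an estimated correlation). Among them were Rps14 (0.99 ± 0.13) and Rpl8 (0.69 ± 0.10), which turned to -0.02 with the offsets and was not called. As a group, 4 of 27 glucocorticoid-induced genes were higher and 1 was lower (3 higher and 1 lower adjusted over the list alone, median 0.30, adjusted p = 0.0778). Lung RNA moved with these groups, since 15 of 16 lung epithelium markers were higher (median 4.57, adjusted p = 1.44e-05 and p = 0.234 with an estimated correlation). An example was Sftpc (5.43 ± 1.13). Mean log2 CPM differed for lung epithelium (2.93), neutrophil (2.64), adipocyte (1.04), B cell (0.98), T and NK cell (0.74), skeletal muscle (0.41) and red cell (-1.34) markers (exact permutation, adjusted p = 0.0265 to 0.0453).

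Calls numbered 6899, 3048 higher and 3851 lower, against 1593 and 5714 on log2(TPM + 1), and 2656 and 2546 with the offsets, which turned the direction of 351. With the offsets Per1 was 0.39 and not called, and Nr3c1 (-0.49), Cenpf (-1.83), Atrx (-1.60), Cenpe (-2.02), Myo9a (-1.54), Mki67 (-1.85), Ifi35 (0.56) and Rps14 (0.35) were smaller, while Per1 lost its call on either TPM scale (0.41 and 0.42) and without BALB/c DTC replicate 5 (0.57) or NSG DTC replicate 1 (0.62) and Sftpc without the 2 lung-rich libraries (2.25), Sftpc was 2.24 and Fkbp5 called (0.35) with the covariate, Fas was 0.58 and Cxcl9 4.99 on log2(TPM + 1), and the glucocorticoid-induced list was called with fry and without BALB/c DTC replicate 3 or 4.

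BALB/c macro-mets (days 21 and 23) were compared with NSG macro-mets (days 19 and 20) for the same question. The antigen presentation and interferon response lists were higher in BALB/c macro-mets (adjusted p = 0.00016 to 0.00363 with an estimated correlation). Fas was higher (1.24 ± 0.23, adjusted p = 0.000931) and Fkbp5 lower (-0.43 ± 0.12, adjusted p = 0.0459) in BALB/c macro-mets. Tsc22d3 (-0.64 ± 0.21, adjusted p = 0.0968), Per1 (-0.74 ± 0.22, adjusted p = 0.0713) and Nr3c1 (0.20 ± 0.21, adjusted p = 0.716) were not called. The 3 largest positive differences were H2-Eb1 (8.86 ± 0.56), H2-Ab1 (7.67 ± 0.64) and H2-Aa (7.15 ± 0.64), and the 3 largest negative ones were the collagen gene Col6a3 (-3.07 ± 0.49), the clock repressor gene Nr1d1 (-1.83 ± 0.34) and the pentraxin gene Nptx1 (-1.80 ± 0.34) (largest adjusted p = 0.00184).

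First, 9 of 10 MHC class II genes were higher (median 6.33, adjusted p = 9.81e-42 and p = 0.00016 with an estimated correlation). Members included Cd74 (5.57 ± 0.37). Next, 18 of 22 MHC class I genes were higher (20 higher adjusted over the list alone, median 0.72, adjusted p = 1.84e-31 and p = 0.00356 with an estimated correlation). These included Psmb9 (1.45 ± 0.18) and Psmb10 (1.28 ± 0.16). Further, 26 of 29 interferon gamma response genes were higher (27 higher adjusted over the list alone, median 2.68, adjusted p = 4.97e-59 and p = 0.00103 with an estimated correlation). They included the GTPase genes Tgtp1 (4.61 ± 0.40) and Igtp (3.32 ± 0.30). Next, 27 of 32 type I interferon response genes were higher (30 higher adjusted over the list alone, median 1.53, adjusted p = 7.09e-44 and p = 0.00363 with an estimated correlation). Among them were Bst2 (1.53 ± 0.20), Cmpk2 (2.16 ± 0.29) and Ifit3 (2.16 ± 0.29). Among single genes, Tnfsf10 (1.65 ± 0.36), which encodes the death ligand TRAIL, Cd274 (1.91 ± 0.32) and the epithelial genes Rab25 (1.48 ± 0.29) and Cldn4 (1.11 ± 0.24) were higher. As a group, 2 of 27 glucocorticoid-induced genes were lower (4 lower adjusted over the list alone, median -0.32, adjusted p = 0.0135 and p = 0.216 with an estimated correlation). Markers of leukocytes were low beside these groups, with Ptprc, which encodes CD45, at 0.469 CPM and Lyz2 at 19.4 CPM against 807 CPM of Cd74 in BALB/c macro-mets. In their lists, 12 T and NK cell markers were tested and 12 were not called (3 higher adjusted over the list alone, median 0.68, adjusted p = 0.0055 and p = 0.209 with an estimated correlation). Next, 5 B cell markers were tested and 5 were not called (1 higher adjusted over the list alone, median 0.94, adjusted p = 0.274). Next, 1 of 21 macrophage and monocyte markers was higher and 1 was lower (1 higher and 2 lower adjusted over the list alone, median -0.41, adjusted p = 0.00816 and p = 0.546 with an estimated correlation). Next, 1 of 9 neutrophil markers was higher (median -0.015, adjusted p = 0.55), with a mean of the opposite sign (0.0067).

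Calls numbered 470, 335 higher and 135 lower, against 549 and 375 with DESeq2, and 463 and 467 with the offsets, under which Tsc22d3 was called (-0.72). Fkbp5 lost its call on log2(TPM + 0.1), without the 4 gene-poor libraries and without any 1 of the 10 libraries (-0.46 to -0.37), Tsc22d3 gained one with DESeq2 (-0.66), voom (-0.57) and without BALB/c macro-met replicate 2 (-0.83), Per1 gained one with DESeq2 (-0.76) and without BALB/c macro-met replicate 2 (-0.85) or NSG macro-met replicate 1 (-0.84) or 2 (-0.88), Nr1d1 was -1.20 with voom and -1.12 without NSG macro-met replicate 3, and the glucocorticoid-induced list was not called with fry, the offsets, without the 4 gene-poor libraries or without NSG macro-met replicate 3, nor the macrophage list with fry, without those 4 or without BALB/c macro-met replicate 1, while the B cell list was called without those 4.

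BALB/c tumours were compared with NSG tumours, which were taken at an earlier day. The antigen presentation and interferon response lists were higher in BALB/c tumours, and the replication, mitosis, NF-kB, immediate early and mesenchymal lists were lower (adjusted p = 0.00556 to 0.224 with an estimated correlation). Fas was higher (1.39 ± 0.23, adjusted p = 3.14e-05) and Fkbp5 lower (-0.45 ± 0.12, adjusted p = 0.00755) in BALB/c tumours. Tsc22d3 (-0.13 ± 0.21, adjusted p = 0.685), Per1 (-0.58 ± 0.22, adjusted p = 0.0594) and Nr3c1 (0.30 ± 0.21, adjusted p = 0.326) were not called. The 3 largest positive differences were H2-Eb1 (10.18 ± 0.59), H2-Ab1 (9.18 ± 0.68) and H2-Aa (8.61 ± 0.68), and the largest negative ones that carried a single ID were Ovol1 (-3.89 ± 0.43) and the bradykinin receptor gene Bdkrb2 (-3.03 ± 0.36) (largest adjusted p = 4.92e-07).

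First, 10 of 10 MHC class II genes were higher (median 7.97, adjusted p = 2.5e-24 and p = 0.00556 with an estimated correlation). Examples were Cd74 (7.32 ± 0.41). Next, 18 of 22 MHC class I genes were higher and 1 was lower (19 higher and 1 lower adjusted over the list alone, median 1.02, adjusted p = 1.6e-17 and p = 0.0329 with an estimated correlation). Members included H2-T22 (1.84 ± 0.14) and Psmb9 (2.31 ± 0.18). Further, 25 of 29 interferon gamma response genes were higher and 1 was lower (median 4.03, adjusted p = 4.14e-29 and p = 0.0196 with an estimated correlation). These included Igtp (4.12 ± 0.31) and Irgm2 (4.36 ± 0.33). Next, 29 of 32 type I interferon response genes were higher (32 higher adjusted over the list alone, median 1.63, adjusted p = 9.16e-22 and p = 0.0496 with an estimated correlation). The ligand genes Cd274 (3.39 ± 0.34) and Tnfsf10 (3.64 ± 0.38) were higher too. Also, 28 of 33 DNA replication genes were lower (31 lower adjusted over the list alone, median -1.01, adjusted p = 1.01e-26 and p = 0.0157 with an estimated correlation). They included Cdc45 (-1.34 ± 0.13) and thymidine kinase, Tk1 (-1.27 ± 0.13). Next, 22 of 30 mitosis genes were lower (24 lower adjusted over the list alone, median -1.07, adjusted p = 9.99e-18 and p = 0.0783 with an estimated correlation). Among them were Aurkb (-2.07 ± 0.20). Further, 14 of 27 NF-kB target genes were lower and 3 were higher (median -0.88, adjusted p = 1.53e-06 and p = 0.224 with an estimated correlation). Examples were Ier3 (-2.04 ± 0.25) and the NF-kB inhibitor gene Tnfaip3 (-2.78 ± 0.33). Also, 16 of 22 immediate early and heat shock genes were lower (median -1.28, adjusted p = 6.27e-10 and p = 0.149 with an estimated correlation). Members included Nr4a1 (-2.89 ± 0.41). Also, 10 of 17 mesenchymal genes were lower (median -0.76, adjusted p = 2.01e-06 and p = 0.0157 with an estimated correlation). These included the matrix protease gene Mmp14 (-1.12 ± 0.11). As a group, 6 of 27 glucocorticoid-induced genes were lower and 5 were higher (6 higher and 8 lower adjusted over the list alone, median -0.058, adjusted p = 0.385). The mean had the opposite sign (0.149), and Hsd11b2 (-2.35 ± 0.22) was lower.

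Calls numbered 4188, 1956 higher and 2232 lower, against 2474 higher and 2360 lower with the offsets. Fkbp5 was -0.29 with the offsets, and Per1 was called with voom, on either TPM scale, with only these libraries, without the 4 gene-poor libraries (-0.87 to -0.55) and without BALB/c tumour replicate 4 (-0.76).

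**Figure D3:**
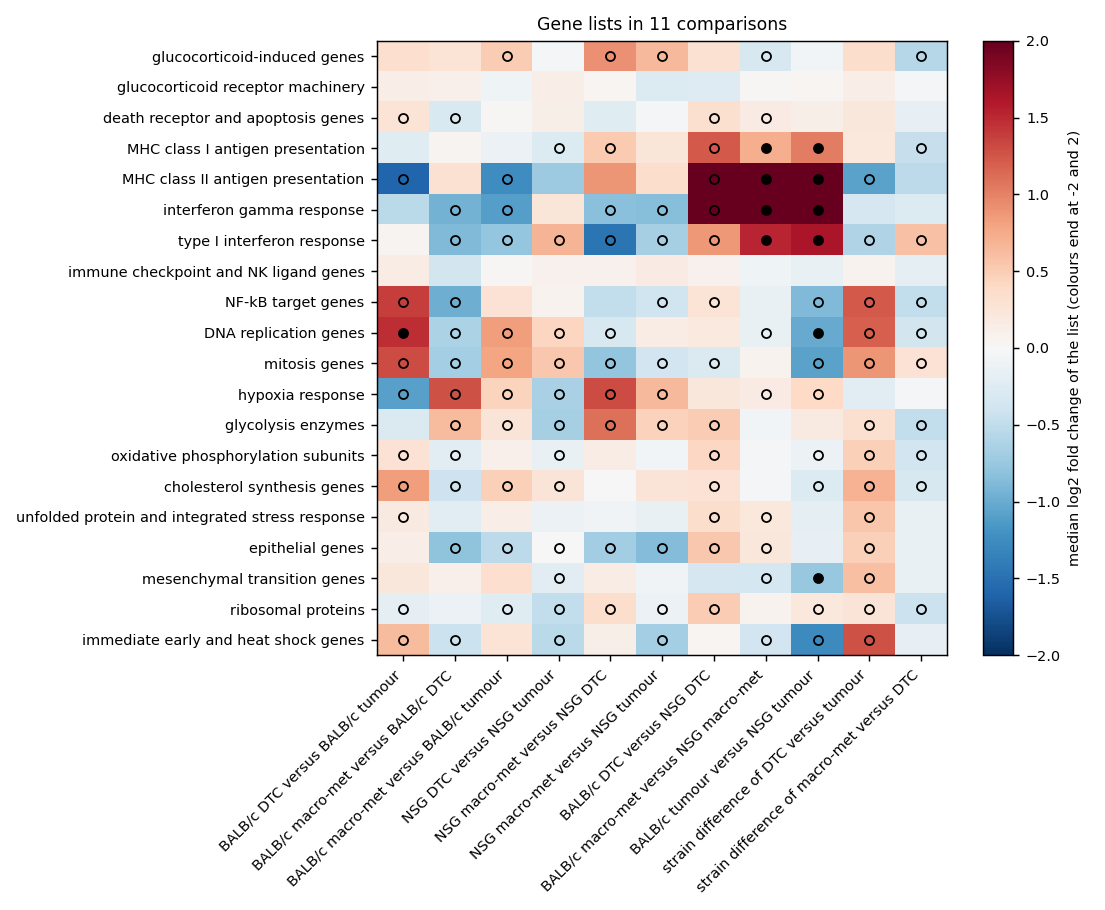
Median log2 fold change of 20 programme lists (lines) in 11 comparisons (columns), with an open circle where camera called the list and a filled circle where it was also called with an estimated correlation. Median MHC class II differences between the strains were 6.69 in DTC, 6.33 in macro-mets and 7.97 in tumours.

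The first interaction asked whether the change from tumour to DTC differed between the strains, and higher here means a more positive change in BALB/c cells. The change was more positive in BALB/c cells for the replication, mitosis, NF-kB, respiratory chain and immediate early lists and more negative for the type I interferon response and MHC class II lists (adjusted p = 0.307 to 0.711 with an estimated correlation). It was more positive for Per1 (1.24 ± 0.32, adjusted p = 0.00303) and Fkbp5 (0.66 ± 0.17, adjusted p = 0.00353) and more negative for Nr3c1 (-1.93 ± 0.30, adjusted p = 1.88e-05). Tsc22d3 (0.05 ± 0.29, adjusted p = 0.913) and Fas (-0.49 ± 0.31, adjusted p = 0.243) were not called. The 5 largest positive differences were Ovol1 (3.67 ± 0.56), the granulocyte growth factor gene Csf3 (2.80 ± 0.37), Fam83a (2.79 ± 0.33), the cytokine gene Lif (2.78 ± 0.43) and Cxcl2 (2.67 ± 0.73). The 5 largest negative differences were Nbeal1 (-4.93 ± 0.54), the thyroid hormone deiodinase gene Dio2 (-4.85 ± 0.50), the nuclear pore gene Ranbp2 (-4.69 ± 0.57), Atrx (-4.60 ± 0.56) and Vps13a (-4.53 ± 0.61) (largest adjusted p = 0.00562 of these 10).

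First, 28 of 33 DNA replication genes were higher and 1 was lower (29 higher and 1 lower adjusted over the list alone, median 1.19, adjusted p = 3.21e-16 and p = 0.307 with an estimated correlation). Among them were Cdc45 (1.73 ± 0.19) and Mcm5 (1.73 ± 0.21). Next, 17 of 30 mitosis genes were higher and 4 were lower (19 higher and 4 lower adjusted over the list alone, median 0.89, adjusted p = 0.000564 and p = 0.651 with an estimated correlation). Examples were Aurkb (2.28 ± 0.27). Further, 17 of 27 NF-kB target genes were higher (median 1.23, adjusted p = 1.69e-06 and p = 0.567 with an estimated correlation). Members included Nfkbie (1.61 ± 0.25). Besides, 20 of 34 oxidative phosphorylation subunits were higher and 1 was lower (26 higher and 1 lower adjusted over the list alone, median 0.47, adjusted p = 1.93e-08 and p = 0.567 with an estimated correlation). These included Cyc1 (1.04 ± 0.13). Also, 11 of 22 immediate early and heat shock genes were higher (median 1.27, adjusted p = 3.13e-05 and p = 0.567 with an estimated correlation). They included Junb (1.90 ± 0.30). Further, 13 of 32 type I interferon response genes were lower (15 lower adjusted over the list alone, median -0.60, adjusted p = 0.0058 and p = 0.711 with an estimated correlation). Among them were Mx1 (-2.70 ± 0.58) and the RNA sensor gene Ifih1 (-3.06 ± 0.57). Next, 3 of 10 MHC class II genes were lower (median -1.07, adjusted p = 0.0328 and p = 0.651 with an estimated correlation). Examples were Cd74 (-1.45 ± 0.44). As a group, 8 of 27 glucocorticoid-induced genes were higher and 2 were lower (median 0.35, adjusted p = 0.0575).

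Calls numbered 5944, 2670 higher and 3274 lower, against 1406 and 4458 on log2(TPM + 1), and 2458 and 2523 with the offsets, under which Nr3c1 (-0.56), Nbeal1 (-2.19), Ranbp2 (-2.81), Atrx (-2.54), Vps13a (-2.37), Cyc1 (0.33), Ifih1 (-2.01) and Junb (1.23) were smaller. Fkbp5 was not called on either TPM scale (0.42 and 0.43), Nbeal1 was -2.74 and Mx1 -1.01 on log2(TPM + 1), Cxcl2 was 4.45 with voom, the glucocorticoid-induced list was called with fry, without the 4 gene-poor libraries and without any 1 of BALB/c tumour replicates 4 and 5, NSG tumour replicate 4 and BALB/c DTC replicates 3 and 4, and the MHC class II list was not called without BALB/c DTC replicate 3.

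The second interaction asked whether the change from DTC to macro-met differed between the strains. The change was more negative in BALB/c cells for the respiratory chain and ribosomal protein lists (adjusted p = 0.702 with an estimated correlation). It was more negative for Per1 (-1.39 ± 0.31, adjusted p = 0.00143) and Fkbp5 (-0.64 ± 0.17, adjusted p = 0.00514) and more positive for Nr3c1 (1.82 ± 0.30, adjusted p = 0.000108). Tsc22d3 (-0.57 ± 0.29, adjusted p = 0.152) and Fas (0.35 ± 0.31, adjusted p = 0.451) were not called. The 3 largest positive differences were Ibsp (4.08 ± 0.55), Cenpf (3.83 ± 0.46) and Tbc1d8b (3.69 ± 0.71), and the negative ones Ttn (-3.94 ± 1.41), Rn7sk (-3.86 ± 1.43) and the glutathione peroxidase gene Gpx3 (-2.68 ± 0.82) (largest adjusted p = 0.0457).

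First, 13 of 30 mitosis genes were higher (median 0.29, adjusted p = 0.0137 and p = 0.702 with an estimated correlation). The cell cycle gene E2f1 (-1.28 ± 0.22) was lower. Further, 8 of 32 type I interferon response genes were higher and 1 was lower (median 0.59, adjusted p = 0.0137 and p = 0.702 with an estimated correlation). Members included Eif2ak2 (2.54 ± 0.49) and Ddx58 (1.13 ± 0.26). Next, 10 of 22 MHC class I genes were lower and 3 were higher (3 higher and 13 lower adjusted over the list alone, median -0.47, adjusted p = 0.00237 and p = 0.702 with an estimated correlation). These included Psmb9 (-1.26 ± 0.25). Besides, 17 of 34 oxidative phosphorylation subunits were lower and 1 was higher (median -0.38, adjusted p = 3.34e-07 and p = 0.702 with an estimated correlation). Next, 18 of 36 ribosomal protein genes were lower (median -0.43, adjusted p = 8.32e-09 and p = 0.702 with an estimated correlation). As a group, 5 of 27 glucocorticoid-induced genes were lower (3 lower adjusted over the list alone, median -0.57, adjusted p = 0.00967 and p = 0.702 with an estimated correlation). The NF-kB subunit gene Nfkb2 (-1.09 ± 0.22) was lower too.

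Calls numbered 5002, 2942 higher and 2060 lower, against 4233 and 760 on log2(TPM + 1), and 1396 and 1943 with the offsets, under which the glucocorticoid-induced and MHC class I lists, Rn7sk (-3.07) and Gpx3 (-2.13) were not called and Nr3c1 (0.47), Cenpf (2.24), Ddx58 (0.74), Nfkb2 (-0.64) and E2f1 (-0.73) were smaller. Ttn and Rn7sk lost their calls with no filter, voom, either TPM scale, the covariate and without the 2 lung-rich libraries (-4.10 to -0.82) and without any 1 of 13 (Ttn) or 15 (Rn7sk) of the 20 libraries, and were -1.34 and -1.40 without NSG macro-met replicate 3, which stood apart in skeletal muscle markers, Gpx3 lost its call without the 2 lung-rich libraries (-1.23) or replicate 1 of them (-1.77) and was -0.93 with the covariate, Tsc22d3 gained one without BALB/c macro-met replicate 2 (-0.76), Fkbp5 was not called on either TPM scale (-0.38 and -0.39), and the mitosis, type I interferon and MHC class I lists were not called with fry, nor mitosis without the 4 gene-poor libraries, nor type I interferon without BALB/c DTC replicate 3.

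Of the genes called in both strains, the change from tumour to macro-met had the same sign for 1807 higher and 1373 lower genes and opposite signs for 82 (1586, 1647 and 123 with GC and length offsets), and the change from DTC to macro-met for 1699 higher, 946 lower and 403 opposite (1808, 1713 and 191). The change from tumour to DTC had the same sign for 738 higher and 617 lower genes and opposite signs for 1201, or 849, 953 and 831 with the offsets.

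**Figure D4:**
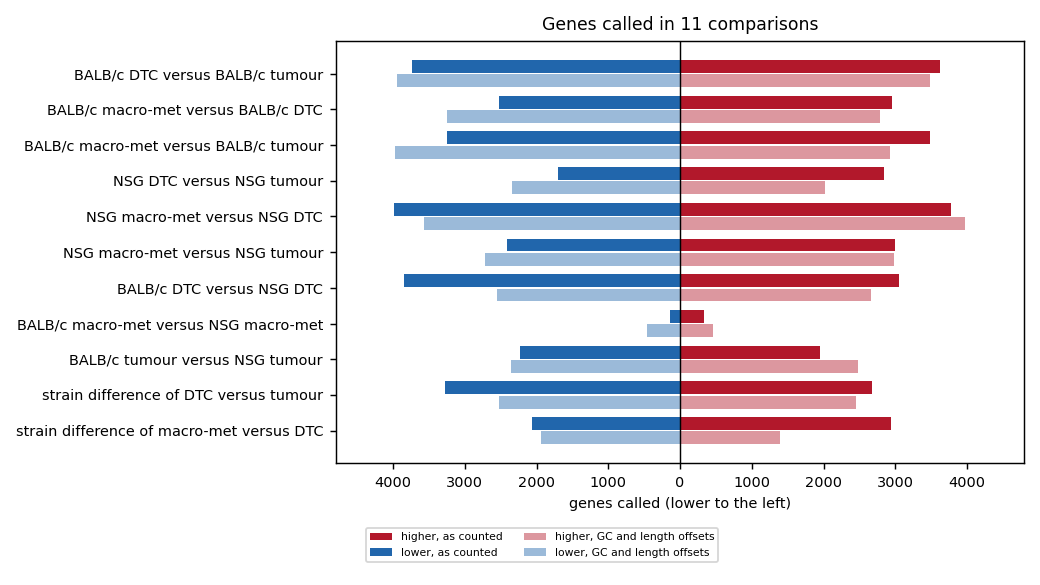
Number of genes called higher (right) and lower (left) in each of the 11 comparisons, as counted and with GC and length offsets. The count ran from 470 between the strains in macro-mets to 7765 between NSG macro-mets and NSG DTC.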

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

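Of the tests below, the splits of the libraries, the length test within the mitosis list and the fit without the libraries that detected the fewest genes were written before their results were seen, and the tests of RNA from other cells, of GC content with length and of handling stress after.

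MHC class II genes were higher in BALB/c than in NSG cells at each stage, and 3 explanations by RNA of other cells or by bias were tested. A larger amount of leukocyte RNA in BALB/c mice was argued against in macro-mets, where 47 leukocyte markers had a median of -0.0148 (upper quartile 0.68) against 3.12 for the lowest called MHC class II gene, and in tumours and DTC, where their upper quartile was at most 2.57 against lower quartiles of 5.52 and 5.30 for MHC class II. Leukocyte RNA still differed there (medians 1.24 and 1.35, with 5 and 16 of 47 markers higher in BALB/c), and the lowest called MHC class II gene in tumours (1.73) lay below the upper quartile of the markers (2.25), so leukocyte RNA is left open for it, although the cells were sorted as CD45-negative. The markers cannot tell whether leukocytes in equal amounts carried more MHC class II RNA in BALB/c mice. RNA of B cells was argued against by their markers, at most 0.117% of Cd74 in a BALB/c macro-met library, 0.203% in DTC and 0.865% in tumours, and GC content with length by a lowest median of 6.23 with the offsets. A response of the 4T1 cells to a host with T, B and NK cells may account for the pattern, as a hypothesis. Other differences between the strains cannot be told apart from it. RNA of lung epithelium, whose markers were higher by 2.93 in BALB/c than in NSG DTC, paralog reads and, for tumours and macro-mets, day were not tested.

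Mitosis genes were higher and ribosomal protein genes lower in NSG DTC than in NSG tumours. GC content with length as the whole cause was argued against by medians that stayed at -0.334 for ribosomal protein genes (quartiles -0.45 and -0.18) and at 0.53 for mitosis genes (lower quartile 0.28) with the offsets. The libraries with the fewest genes were argued against by camera without them (larger adjusted p = 1.02e-05), though with all libraries neither list was called with an estimated correlation (mitosis adjusted p = 0.431, ribosomal adjusted p = 0.386). An effect of transcript length within the mitosis list cannot be told apart from growth, since the 15 shorter genes had a median of 0.341 and the 15 longer ones 1.27, and the log2 fold change rose with length (rank correlation 0.547, permutation p = 8e-04). Day, injection route and organ were not tested.

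Fkbp5 and Tsc22d3 were higher in macro-mets than in DTC in both strains. RNA of lung epithelium was argued against in BALB/c mice by its markers (median -4.09, upper quartile -1.19), below gene rises of 0.87 and 1.34. In NSG mice its markers could not decide by the rule, which asked for a negative upper quartile (median -0.0183, quartiles -0.415 and 0.471). Those markers showed no rise on balance, and their upper quartile lay below gene rises of 1.51 and 1.91. Other lung cells cannot be told apart there, as neutrophil markers rose by 1.33 (exact permutation, adjusted p = 0.0397). GC content with length was argued against by values of 0.698 and 1.22 in BALB/c and 1.28 and 1.87 in NSG mice with the offsets. Handling stress cannot be told apart from a hormone response, because immediate early and heat shock genes moved both ways in BALB/c mice (median -0.436, upper quartile 0.26, adjusted p = 0.0165, adjusted p = 0.66 with an estimated correlation) and in NSG mice (median 0.11, adjusted p = 0.878). A higher glucocorticoid level at the late stage may be an explanation, but in BALB/c mice the glucocorticoid-induced list (adjusted p = 0.338) and Per1 (-0.44) were not called, nor was the list in NSG mice with the offsets, and day and hour of death were not tested.

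In each of the 11 comparisons, 1 of 100 splits of the same libraries, the real split itself, called as many genes. The smallest share that 100 splits can give is 1 in 100, so a chance result was made unlikely, not excluded. The splits cannot tell an effect of group apart from one of the numbers in the library titles. In the order of the report, the real split called 5160, 5356, 5466, 5725, 7828, 5935, 7081, 887, 3680, 5890 and 5663 genes and the highest other split 0, 166, 802, 0, 0, 0, 0, 68, 0, 3384 and 0.

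Among 126 sets of 5 libraries, 14 had a library far from the others, where chance gives about 1 in 20. BALB/c tumour replicate 4 stood apart in its rank correlation with length (-0.201, others 0.0382 to 0.129) and in mean log2 CPM of endothelial (0.262, others -1.3 to -1.04), adipocyte (0.891, others -2.4 to -1.67) and skeletal muscle markers (4.32, others 1.03 to 1.56). NSG macro-met replicate 3 did so in skeletal muscle markers (3.2, others 0.381 to 0.74), NSG macro-met replicate 1 in lung epithelium markers (-0.311, others 0.55 to 0.882), BALB/c macro-met replicate 2 in adipocyte markers (-3.17, others -2.7 to -2.52) and NSG tumour replicate 2 in T and NK cell markers (-1.76, others -2.4 to -2.25). Total counts were 60.3 M (M for mega) in BALB/c DTC replicate 5 (others 35.2 to 39.2) and 34.6 M in NSG DTC replicate 5 (others 54.2 to 57.8). BALB/c DTC replicate 1 had counts for 21575 genes (others 19563 to 20131), and 3.84% of the counts of BALB/c tumour replicate 5 were mitochondrial (others 2.05 to 2.56). Tsc22d3 stood at 163 CPM in BALB/c DTC replicate 5 (others 81.3 to 88.2) and at 65.3 CPM in NSG tumour replicate 1 (others 56.4 to 58.6).

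By the interaction term, the change from tumour to DTC differed between the strains for 46 named genes (log2, BALB/c minus NSG). Called in opposite directions in the strains were Fkbp5 0.66, Nr3c1 -1.93, Junb 1.90, Hsd11b2 2.09, Ovol1 3.67, Csf3 2.80, Nbeal1 -4.93, Dio2 -4.85, Ranbp2 -4.69, Atrx -4.60 and Vps13a -4.53. Called in the same direction in both were Per1 1.24, Stra6 1.82, Tnf 1.53, Wnt10a 1.08, Ibsp -3.57, Bnip3 -1.54, Boc -1.67, Mcm10 1.57, Cdc45 1.73, Mcm5 1.73, Aurka 1.63, Icam1 1.40 and Sqle 0.76. Called in BALB/c alone were Cxcl2 2.67, Gpnmb -3.58, Aurkb 2.28, Nfkb2 1.32, Bnip3l -1.07, H2-Eb1 -1.82, Cd74 -1.45, Fam83a 2.79, Lif 2.78, Nfkbie 1.61 and Cyc1 1.04. Called in NSG alone were Mki67 -3.08, Kif20b -3.27, Cenpf -3.25, Cenpe -3.13, Fosb 2.35, Mx1 -2.70, Ddx58 -0.88, Rps18 0.46, Rpl13 0.52, Fos 1.49 and Ifih1 -3.06. The change from DTC to macro-met differed for 29. Of these, E2f1 -1.28 was called in opposite directions and Rn7sk -3.86 in neither strain. In the same direction in both were Fkbp5 -0.64, F5 2.77, Serpina3g -2.29, Bnip3l 1.01, Nfkb2 -1.09, Socs1 -0.98, Mcm5 -0.88, Cdc45 -0.59, Cenpe 3.50, Smc2 3.35, Aspm 3.68, Arrdc2 -0.88, H2-K1 -0.72, Ifit1 1.75, Cenpf 3.83, Mki67 3.02 and Ddx58 1.13. In BALB/c alone were Sftpc -4.66, Ibsp 4.08 and Gpx3 -2.68, and in NSG alone Per1 -1.39, Nr3c1 1.82, Eif2ak2 2.54, Tbc1d8b 3.69, Ttn -3.94, Psmb8 -0.996 and Psmb9 -1.26. With GC and length offsets 59 of the 75 were called with the same sign and 16 were not called. The grouping by strain is without the offsets, with which Fkbp5, Nr3c1, Hsd11b2 and Vps13a were not called from tumour to DTC in BALB/c mice, nor Ovol1 and Csf3 in NSG mice, nor E2f1 from DTC to macro-met in NSG mice.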

How the results depend on the processing

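The fits with offsets and without gene-poor or lung-rich libraries were chosen after seeing the data. In the order of the report, a fold of at least 2, which is stricter by construction, left 3105, 1915, 2974, 1799, 3593, 1999, 2549, 252, 1573, 3068 and 2394 genes. NSG DTC against tumours gave 6953 with voom, and BALB/c against NSG macro-mets 924 with DESeq2, 1986 with voom, 887 with only their libraries and 930 with the offsets, and the cause was not tested. Other counts stayed within 1.5 times. Leaving out 1 library gave, in that order, 6521 to 7565, 4726 to 5665, 5570 to 6787, 3717 to 4233, 7088 to 7524, 4521 to 5063, 6228 to 6988, 327 to 443, 3337 to 4228, 5400 to 6427 and 4163 to 5231. Of 276 named gene results, 229 kept direction and call throughout. With the offsets 266 did, 8 lost and 1 gained a call, and Rpl8 in BALB/c against NSG DTC reversed to -0.02051, for a cause not tested. Of 99 list results, 76 lost a call with an estimated correlation and 23, many uncalled both ways, did not. Fry lost 8 calls and gained 6, and the offsets lost 6. The median of all genes moved by up to 0.271 on log2(TPM + 0.1), -0.138 with the offsets and 0.103 with only the libraries of a comparison.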

Other observations

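Other lists were compared between BALB/c and NSG DTC with tests chosen beforehand. Here 14 of 28 death receptor and apoptosis genes were higher and 5 were lower (median 0.33, adjusted p = 0.00739 and p = 0.23 with an estimated correlation). Likewise 9 of 19 unfolded protein and stress response genes were higher and 3 were lower (median 0.35, adjusted p = 0.00865 and p = 0.234 with an estimated correlation). In the receptor group, 5 of 13 glucocorticoid receptor machinery genes were lower and 2 were higher (median -0.26, adjusted p = 0.487). In the checkpoint group, 6 of 16 immune checkpoint and NK ligand genes were lower and 3 were higher (5 higher and 6 lower adjusted over the list alone, median 0.093, adjusted p = 0.842), with a mean of the opposite sign (-0.0204). These 2 lists were called with fry.

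Between the macro-mets of the strains, 18 fibroblast, pericyte and smooth muscle markers were tested and 18 were not called (1 lower adjusted over the list alone, median -0.48, adjusted p = 0.0372 and p = 0.546 with an estimated correlation). The call was lost with fry, with the offsets, without the 4 gene-poor libraries and without BALB/c macro-met replicate 1 or 2 or NSG macro-met replicate 2 or 3. Likewise 7 skeletal muscle markers were tested and 7 were not called (5 lower adjusted over the list alone, median -1.98, adjusted p = 0.00564 and p = 0.427 with an estimated correlation), a call lost with fry and without NSG macro-met replicate 3. Lastly, 4 adipocyte markers were tested and 4 were not called (median -0.57, adjusted p = 0.375), and 8 red cell and platelet markers were tested and 8 were not called (median 0.15, adjusted p = 0.982), with a mean of the opposite sign (-0.058).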
